A study of Mus musculus with 20 samples.

How the data were processed

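RNA from 10 sorted populations of haematopoietic cells of C57BL/6 mice was measured on Affymetrix Mouse Genome 430 2.0 arrays, with 2 biological replicates per population and 20 arrays in all. Per the labels' protocols, total RNA was extracted with ISOGEN, and biotin-labelled cRNA was made from the RNA of 3000 cells with a kit that amplifies in 2 cycles. The tissue the cells came from, the animals behind each replicate and the gates beyond the named surface markers are not given in the sources used here. The populations are called KSL, LinNeg (negative for lineage markers), B (B220-positive), CD4T, CD8T, NK (NK1.1-positive), NKT (positive for CD3ε and NK1.1), Erythroblast (Ter119-positive), Neutrophil (Gr-1-positive) and Monocyte (Mac-1-positive, named monocytes/macrophages by the labels). Groups and replicate numbers were taken from the sample titles.

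The deposited values are linear probe set intensities, 1 per probe set and array, from 0.0251 to 19431. The software that summarised the probes, its background correction and its scaling are not given in the sources used here. In each of the 20 arrays the mean of the deposited intensities without the lowest and highest 2% was 100, so the arrays had been brought to one scale; the values are not centred per gene and carry no ratio, so their direction is not in doubt. The median intensities of replicates 1 and 2 were 22.9 and 22.3 in KSL, 20.5 and 23.2 in LinNeg, 22.7 and 22.5 in B, 24.4 and 26.8 in CD4T, and 24.9 and 22.4 in CD8T. They were 22.1 and 23.3 in NK, 24.3 and 26.5 in NKT, 22.4 and 20.3 in Erythroblast, 21.3 and 21.0 in Neutrophil, and 21.7 and 24.0 in Monocyte. Such a scaling sets the trimmed mean of every array equal, while the 100 brightest probe sets held from 9.16% to 15.8% of the signal, so a population with less RNA per cell, or with signal held by fewer genes, is not seen as lower throughout. Amplification in 2 cycles favours the 3′ ends of transcripts. The ratio of the 3′ to the 5′ control probe set for Gapdh ran from 2.36 to 6.10 over the arrays and that for Actb from 1.34 to 2.73. The precision is limited by the 2 arrays per population.

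From these values log2(intensity + 6.75) was computed, where the pseudocount is the 25th percentile of all values, and the deposited scaling was kept, since the array medians spanned 0.314 on the log2 scale. A fold change on this scale understates the change of dim genes. Of 45101 probe sets, 64 were controls and were left out. By the platform annotation, 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none, and only those with 1 symbol were used for genes. The symbols were updated by Entrez number through the RefSeq table of GRCm38.p6, which changed 0 of them and left 204 without a match under the name in the annotation. For each of 18193 genes the probe set with the highest mean was kept, and 14044 genes whose highest population mean lay above the median of all values (4.89 on the log2 scale) were tested.

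All 20 arrays were fitted in one limma model (version 3.58.1, R 4.3.3) with 1 factor of 10 levels, using lmFit and eBayes with a mean-variance trend. The model had 10 residual degrees of freedom and 8.46 prior degrees of freedom. The 9 contrasts were fixed in advance, and in a contrast with several populations on a side each population had equal weight on the log2 scale. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg within the contrast) with an absolute log2 difference of at least 1. A gene was called restricted to a population when it was called higher there than in each of the others. An F test over the 10 populations was made in the same model. A set of 33 gene lists with 516 members, covering lineages, proliferation, chromatin and responses, was written down beforehand; 455 members were tested. Lists were tested with camera at a preset correlation of 0.01 and adjusted over 297 pairs of list and contrast. An estimated correlation and fry, which asks whether a list moves one way on balance without comparing it with other genes, were run beside it. Similarity of arrays was the Pearson correlation across the genes tested, which are not independent replicates.

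Named genes followed a rule. They are the genes with the largest differences in each direction (10 for the contrasts of KSL, 8 for the others) among called genes above the median level. Their compared arrays, or in contrasts of several populations the population means, do not overlap. Genes with uncharacterised symbols were passed over. Members of the lists, the genes of the sort markers, and the 5 restricted genes per population with the largest gap to the next population could be named as well. Of 152 named pairs of gene and contrast, 66 had another probe set above the filter and 1 had a probe set with the opposite sign. In 32 pairs the gene was read by a probe set of the kinds marked _x_at or _s_at, which can bind related transcripts.

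The steps were tested on simulated data made from the real gene means and variances of the 14044 genes, with 100 genes changed at each of 2 sizes. Noise was drawn independently for each gene around its mean over all arrays. The simulation therefore held no correlation between genes and does not show how the list test behaves with it. At a log2 difference of 2, the share of changed genes recovered was 74% for KSL against LinNeg, 87% for KSL against mature, 98% for lymphoid against myeloid, 80% for B against T, 80% for CD4T against CD8T, 78% for NK against NKT, 83% for NKT against T, 69% for Neutrophil against Monocyte and 91% for Erythroblast against the other mature populations. At a log2 difference of 4, it was 99% for KSL against LinNeg, CD4T against CD8T and NK against NKT, and 100% for the 6 other contrasts. Between 0 and 11 unchanged genes were called per contrast. In a simulation where 1 list was raised by a log2 difference of 1 in KSL, and 200 random genes by 4, the list test called that list and 1 other list in KSL against LinNeg. Whether that other list held some of the 200 genes was not checked.

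The alternatives tried were quantile normalization and array median centring, the pseudocount, the filter on dim genes, the mean of all probe sets, the variance model, array weights, the arrays in the fit, a replicate block, the minimum log2 difference and leaving out each array in turn. Most were fixed before the data were examined. Python 3.11.15 with matplotlib 3.10.9 drew the figures. No scan date or batch label was used here.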

Results

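Gene expression was measured in 10 populations of mouse haematopoietic cells sorted by surface markers. KSL is the usual name for a fraction enriched in haematopoietic stem and early progenitor cells, and LinNeg is the broader fraction without markers of mature lineages. The 8 mature populations were B cells, CD4 and CD8 T cells, NK cells, NKT cells, erythroblasts, neutrophils and monocytes/macrophages. Each population had 2 biological replicates, for 20 arrays. Values are probe set intensities scaled to a trimmed mean of 100, given as mean ± SD (n = 2), and differences are on the log2(intensity + pseudocount) scale with their limma standard error. The share of probe sets above an intensity of 100 ran from 19.4% to 25.3% over the arrays and was lowest in Erythroblast, at 19.6%. The labels call the replicates biological without naming animals. The p-values and standard errors rest on the spread between arrays of the same population, pooled over the populations. In contrasts with several populations on a side, the spread among those populations does not enter them. Such p-values therefore do not show that a difference holds across the populations of a lineage.

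The genes of the surface markers used for sorting were read first, as a check of the labels. Cd4 had an intensity of 392 ± 41.6 in CD4T and 3.48 ± 0.214 in CD8T. Cd8a stood at 258 ± 8.24 in CD8T, 46.4 ± 33.7 in CD4T and 137 ± 69.0 in Erythroblast. Cd3e, a chain of the T cell receptor complex, was at 547 ± 114 in CD4T, 578 ± 235 in CD8T and 599 ± 136 in NKT, and at 25.9 ± 21.7 in NK. Kit, the stem cell factor receptor, was at 1300.5 ± 136 in KSL and 739 ± 18.8 in LinNeg. Itgam, which encodes a chain of Mac-1, was at 455 ± 70.9 in Monocyte, 767 ± 66.7 in Neutrophil and 116 ± 21.9 in NK. Ptprc, which encodes CD45 and its B220 isoform, was at 1.85 ± 1.17 in Erythroblast and 4872 ± 176 in B, below its 6615 ± 152 in CD8T, so the gene does not check the B220 sort. The genes of Sca-1, NK1.1 and Gr-1 (Ly6a, Klrb1c and Ly6g) had no probe set with that symbol alone.

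The 2 arrays of each of the 10 populations correlated best with each other, with Pearson r across genes from 0.953 to 0.972. Erythroblast stood farthest from the rest, and its highest r with an array of another population was 0.708, with LinNeg. The closest arrays of different populations were NKT and CD8T, at 0.948. CD4T and CD8T reached 0.942, KSL and LinNeg 0.939, and Neutrophil and Monocyte 0.931. NK arrays had an r of up to 0.886 with NKT and up to 0.868 with Monocyte. Of 14044 genes tested, 10742 (76.5%) differed among the 10 populations in the limma F test.

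**Figure D1:**
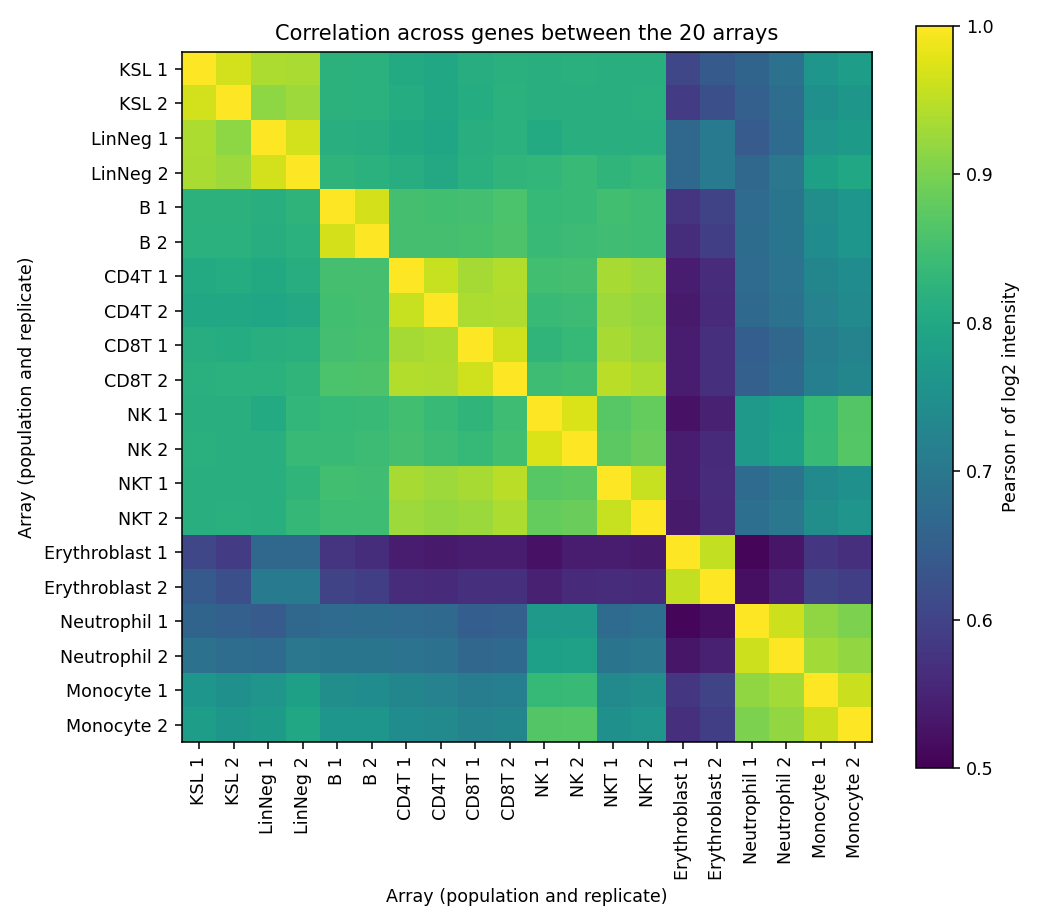
Pearson correlation across genes between all 20 arrays, with each row and column 1 array named by population and replicate and the colour giving r of log2 intensities from 0.5 to 1. The 2 arrays of every population form the brightest block, NK shares a raised correlation with Monocyte (up to 0.868), and Erythroblast stands apart, with its highest r at 0.708.

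KSL was compared with LinNeg to ask which genes set the stem-enriched fraction apart from the lineage-negative cells as a whole. Genes of the stem and progenitor list rose in KSL. Among them Hlf, a transcription factor of stem cells, was at 1189.5 ± 625 in KSL and 166 ± 94.9 in LinNeg (log2 difference 2.80 ± 0.56, limma adjusted p 0.0040). Procr, the endothelial protein C receptor used as a stem cell marker, differed by 2.53 ± 0.53 (adjusted p 0.0055), and Meis1 by 2.32 ± 0.39 (adjusted p 0.00088). Among the genes named by rule, Fgd5 had the largest rise, at 181 in KSL and 9.33 in LinNeg (3.49 ± 0.50). Its LinNeg level is near the pseudocount of 6.75, so the size of this rise depends on it. Col4a1, Cadps2 and Cdcp1 rose by 3.03 ± 0.42, 2.89 ± 0.38 and 2.82 ± 0.40. LinNeg was higher in the antibody genes Jchain, at 2958 ± 255 against 12.1 ± 2.39 in KSL, and Igha, at 5039 ± 1091 against 37.1 ± 1.45, while the plasma cell list was not called (2 of 7 genes lower in KSL, 2 adjusted over the list alone, camera adjusted p 0.084). It was also higher in Ccl5, a chemokine of cytotoxic lymphocytes (log2 difference KSL minus LinNeg -5.45 ± 0.29), and in Gimap4 and Ms4a4b (-4.58 ± 0.23 and -4.52 ± 0.47).

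By list, 10 of 26 stem and progenitor genes rose in KSL and 0 fell, or 14 adjusted over the list alone (camera adjusted p 6.6e-10, and adjusted p = 0.0013 with an estimated correlation). Of 22 erythroid genes, 14 fell and 0 rose, 15 adjusted over the list alone (adjusted p 1.3e-14, and 0.017 with an estimated correlation). These included Car1, a carbonic anhydrase of early red cells, at 416 in KSL and 5484 in LinNeg, and Klf1, the erythroid transcription factor, at 150.1 and 1890.4. Heme biosynthesis genes fell in 5 of 10, 6 adjusted over the list alone (adjusted p 3.7e-07, and 0.035 with an estimated correlation). Genes of NK and T cells were lower too, while of 21 B cell genes 1 rose and 0 fell, 1 and 0 adjusted over the list alone (adjusted p 0.87), and of 10 CD4 T cell genes 1 fell, 1 adjusted over the list alone (adjusted p 0.96). Of 22 NK and cytotoxic genes 11 fell, 13 adjusted over the list alone (adjusted p 1.6e-13, and 0.017 with an estimated correlation), and of 17 pan T cell genes 7 fell and 1 rose, 9 and 1 adjusted over the list alone (adjusted p 2.3e-08, and 0.0023 with an estimated correlation). Monocyte genes fell in 9 of 18, 12 adjusted over the list alone (adjusted p 4.6e-10, but adjusted p = 0.12 with an estimated correlation). Interferon response genes rose in 5 of 17, 6 adjusted over the list alone, among them Oasl2 at 200.3 in KSL and 50.7 in LinNeg (adjusted p 1.7e-06, but adjusted p = 0.10 with an estimated correlation).

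In all, 745 genes were called between KSL and LinNeg, 415 higher and 330 lower in KSL. The split depended on the settings, with 374 higher and 368 lower under quantile normalization, 359 and 356 after array median centring, and 262 and 278 with a pseudocount at the 5th percentile. The count was 293 without KSL replicate 2 (114 higher and 179 lower) and 357 without LinNeg replicate 1 (117 higher and 240 lower), and 68 when the test asked for a log2 difference above 1. Without one or both of these arrays Vldlr, Dntt, Mamdc2, Slc16a12, Upp1 and Il1r1, which are among the 10 named rises, were no longer called, with adjusted p from 0.053 to 0.12. The call of Dntt also ended with a pseudocount at the 5th percentile (log2 difference 2.90, adjusted p 0.11).

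KSL was also set against the mean of the 8 mature populations. Hoxa9, a homeobox gene of progenitors, was at 2059 ± 151 in KSL and at a mean of 13.3 in the mature populations (log2 difference 7.02 ± 0.47, limma adjusted p 1.7e-09). Cd34, a surface marker of progenitors, rose by 6.98 ± 0.38, Dntt, which encodes terminal transferase, by 7.01 ± 0.47, and Angpt1, a ligand of the Tie2 receptor, by 6.54 ± 0.29. Mpo and Prtn3, enzymes of primary neutrophil granules, rose by 5.70 ± 0.40 and 5.80 ± 0.43 against the mature mean. The primary granule list as a whole had a lower mean log2 level in KSL (9.18) than in Monocyte (10.07). It stood at 9.70 in KSL replicate 1 and 8.66 in replicate 2. Among the genes that fell were Gimap4, at a mean of 3245 in the mature populations (-5.04 ± 0.17), Lgals3 (-4.99 ± 0.53), Ikzf3, a lymphoid transcription factor (-4.11 ± 0.24), and Ltf, lactoferrin of secondary granules (-4.07 ± 0.42). Gimap4 was uneven among the mature populations. Its mean was 5180 over B, CD4T, CD8T, NK and NKT, and 21.8 over Neutrophil and Monocyte. Its difference of -5.04 is therefore an average and does not hold at that size for each mature population.

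Of 26 stem and progenitor genes, 22 rose and 0 fell, 22 adjusted over the list alone (camera adjusted p 5.4e-14, and 0.00049 with an estimated correlation). Ribosome biogenesis genes rose in 17 of 22, 17 adjusted over the list alone (adjusted p 7.4e-11, but adjusted p = 0.051 with an estimated correlation). Gnl3, a nucleolar GTP-binding protein, was at 1232 in KSL and 334 in the mature populations (2.36 ± 0.15), and Gar1, a snoRNP component, differed by 2.25 ± 0.18. DNA replication genes rose in 17 of 23, 17 adjusted over the list alone, with Mcm2, a subunit of the replicative helicase, at 2.26 ± 0.15 (adjusted p 3.5e-08, but adjusted p = 0.28 with an estimated correlation). The mean log2 level of this list was nevertheless higher in Erythroblast (10.56) than in KSL (9.36). The ribosome biogenesis list stood at 9.07 in KSL, and in the mature populations from 5.64 in Neutrophil to 8.80 in CD8T. Of 10 DNA methylation genes, 5 rose and 1 fell, 5 and 1 adjusted over the list alone (adjusted p 0.026, but adjusted p = 0.28 with an estimated correlation). That call ended with the filter at the 75th percentile (adjusted p 0.095). In this list the methyltransferase Dnmt3b stood at 1095 ± 168 in KSL (3.34 ± 0.21), Tet1 rose by 2.71 ± 0.35, and the methyl-CpG binding protein gene Mbd2 fell by 1.54 on the log2 scale. Secondary and tertiary granule genes fell in 11 of 13 and 1 rose, 11 and 1 adjusted over the list alone (adjusted p 5.4e-06, but adjusted p = 0.28 with an estimated correlation). NK and cytotoxic genes fell in 17 of 22, 17 adjusted over the list alone (adjusted p 4.7e-12, and 0.020 with an estimated correlation). Neither list was lower in KSL than in every mature population. The granule list stood at 4.70 in KSL and from 4.09 in CD8T to 13.26 in Neutrophil, with Erythroblast (4.31) also below KSL. The NK and cytotoxic list stood at 4.83 in KSL and from 4.39 in B to 10.10 in NK, with Erythroblast (4.49) also below KSL. A total of 3184 genes were called, 2219 higher and 965 lower in KSL. The contrast weighs the 8 populations equally on the log2 scale, so the mean intensity of a gene that is very high in 1 of them can exceed the level in KSL while its log2 difference is positive, as for Elane (1.56, 242 in KSL and 367 in the mature mean); the treat test against a log2 difference of 1 called 983.

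The lymphoid populations (B, CD4T, CD8T, NK and NKT) were compared with the myeloid ones (Neutrophil and Monocyte). Cd2, an adhesion receptor of lymphocytes, was at a mean of 2171 in the lymphoid and 1.82 in the myeloid populations (log2 difference 7.82 ± 0.12, limma adjusted p 5.7e-19). The named rises included Gimap4 at 7.32 ± 0.13, Gimap8 at 7.09 ± 0.18, Gimap6 at 6.51 ± 0.17 and Gimap7 at 6.23 ± 0.21. They belong to a family of lymphocyte GTPases that was not tested as a group. Bcl2, which blocks apoptosis, rose by 6.38 ± 0.26. Granule and secreted genes of neutrophils were lower in lymphoid cells, with Lcn2 at 228 against 12097 (-8.84 ± 0.46), Cd177 (-8.48 ± 0.36), Camp, the cathelicidin (-8.33 ± 0.59), Mmp8 (-8.10 ± 0.25) and Hp (-8.20 ± 0.25).

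All 13 secondary and tertiary granule genes fell in lymphoid cells, 13 adjusted over the list alone (camera adjusted p 6.4e-12, but adjusted p = 0.11 with an estimated correlation), and so did all 9 mature neutrophil receptor genes, 9 adjusted over the list alone (adjusted p 4.0e-09, and 0.018 with an estimated correlation). Of 17 pan T cell genes, 16 rose, 16 adjusted over the list alone (adjusted p 8.1e-09, and 0.0020 with an estimated correlation). Ribosome biogenesis genes rose in 21 of 22, 21 adjusted over the list alone (adjusted p 4.1e-10, but adjusted p = 0.057 with an estimated correlation), and Fbl, the nucleolar methyltransferase fibrillarin, was at 1403 against 141 (3.49 ± 0.18). Mitosis genes fell in 22 of 23, 22 adjusted over the list alone (adjusted p 1.7e-12, but adjusted p = 0.14 with an estimated correlation), with Ube2c at 62.9 against 569.6 (-3.15 ± 0.22) and Mki67 at 426 against 2383 (-2.59 ± 0.23). DNA replication genes were not called as a list, with 1 of 23 higher and 2 lower, 1 and 2 adjusted over the list alone (adjusted p 0.76). The mean log2 level of this list was 6.52 in Neutrophil and 8.80 in Monocyte. All lymphoid populations lay between them, from 7.33 in CD4T to 8.30 in B. The contrast therefore averages differences of opposite sign and does not show like levels on the 2 sides. Polycomb repressive complex 1 genes rose in 8 of 17, 8 adjusted over the list alone (adjusted p 0.017, but adjusted p = 0.16 with an estimated correlation). Among them Cbx7 was at 219.7 against 16.0 (3.24 ± 0.19) and Bmi1 at 436 against 110 (2.15 ± 0.13). Of 18 monocyte and macrophage genes 8 fell and 1 rose, 8 and 1 adjusted over the list alone (adjusted p 0.0067, but adjusted p = 0.50 with an estimated correlation), and the NK arrays, which are on the lymphoid side, held this list at a mean log2 level of 10.83, above the 9.89 of Monocyte. In total 4124 genes were called, 2448 higher and 1676 lower in the lymphoid populations, and 4415 with NK left out, an alternative chosen after seeing the data. The median of all genes lay at 0.10 and shifted by -0.10 under quantile normalization, and treat called 2421. The control ratios of 3′ to 5′ signal differed between the sides, with population means for Gapdh from 3.60 to 5.32 in the lymphoid and 2.42 to 3.22 in the myeloid populations, and for Actb from 1.76 to 2.49 and 1.35 to 1.45.

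**Figure D2:**
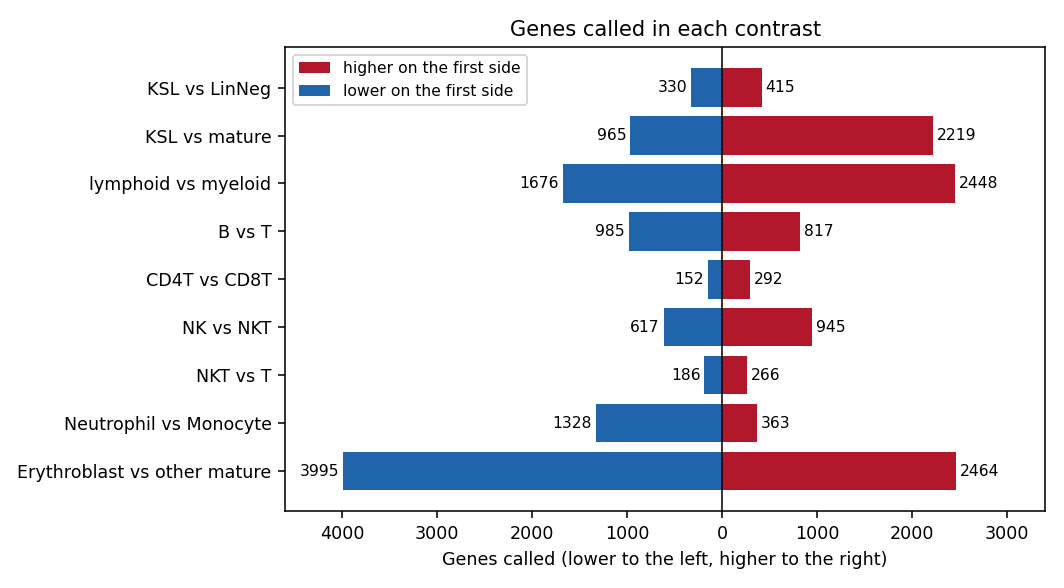
Number of genes called in each of the 9 contrasts (limma, adjusted p under 0.05 and absolute log2 difference of at least 1), with bars to the right for genes higher and bars to the left for genes lower on the first-named side. The counts run from 444 in CD4T vs CD8T to 6459 in Erythroblast vs other mature.

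B cells were compared with the mean of CD4 and CD8 T cells. Ms4a1, which encodes CD20, was at 8068 in B and 8.66 in T cells (log2 difference 9.14 ± 0.39, limma adjusted p 2.2e-12). MHC class II genes rose, with H2-Aa at 8.61 ± 0.48 and H2-Ab1 at 8.18 ± 0.45, as did the transcription factor gene Spib, at 4075 against 9.63, Cd24a (7.93 ± 0.31) and Scd1, a fatty acid desaturase (7.88 ± 0.48). T cells were higher in Cd3d (-8.23 ± 0.29), the transcription factor gene Bcl11b (-8.14 ± 0.35), Ccl5 (-8.15 ± 0.25), Prkcq, a kinase of T cell receptor signalling (-7.34 ± 0.24), and Thy1 (-7.12 ± 0.26).

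Of 21 B cell genes, 19 rose, 19 adjusted over the list alone (camera adjusted p 1.3e-30, and 0.0013 with an estimated correlation), and all 9 MHC class II presentation genes rose, 9 adjusted over the list alone (adjusted p 8.5e-18, and 0.0047 with an estimated correlation). Pan T cell genes fell in 15 of 17, 15 adjusted over the list alone (adjusted p 2.6e-23, and 0.00017 with an estimated correlation). Plasma cell genes rose in 4 of 7 and fell in 1, 4 and 1 adjusted over the list alone (adjusted p 0.0012, and 0.040 with an estimated correlation); Jchain and Mzb1 rose by 4.54 ± 0.77 and 5.97 ± 0.31, and Prdm1 fell by 1.39 on the log2 scale. Mitosis genes rose in 11 of 23, 11 adjusted over the list alone (adjusted p 8.1e-09, but adjusted p = 0.23 with an estimated correlation), with Nusap1 at 192 in B and 31.2 in T cells. Interferon response genes fell in 8 of 17, 8 adjusted over the list alone (adjusted p 0.0054, but adjusted p = 0.32 with an estimated correlation), with Ifih1, an RNA sensor, at 44.7 in B and 377 in T cells. The contrast called 1802 genes, 817 higher and 985 lower in B, and treat called 726. After array median centring 918 were higher and 860 lower.

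CD4 and CD8 T cells were compared with each other. Beside Cd4 itself (5.28 ± 0.52), CD4T was higher in Ctla4, an inhibitory receptor, at 1304 ± 295 against 25.9 (log2 difference 5.85 ± 0.64, limma adjusted p 1.8e-05), in the transcription factor gene Maf (5.58 ± 0.35), in Nrp1 (4.82 ± 0.46) and in Foxp3, the transcription factor of regulatory T cells, at 331 ± 20.6 against 16.5 (3.86 ± 0.41). Cd8b1, which encodes a chain of CD8, was at 2164 ± 110.3 in CD8T and 49.3 in CD4T (-5.45 ± 0.55), and Crtam (-2.86 ± 0.46) and the Ly49 receptor gene Klra7 (-3.08 ± 0.35) were also higher in CD8T. Of 10 CD4 T cell genes 8 rose, 9 adjusted over the list alone (camera adjusted p 1.1e-15, and 0.00048 with an estimated correlation), and of 8 CD8 T cell genes 6 fell, 6 adjusted over the list alone (adjusted p 3.3e-11, and 0.0013 with an estimated correlation). NKT and innate-like T genes rose in 6 of 12 in CD4T, 7 with 1 lower adjusted over the list alone (adjusted p 1.9e-05, and 0.047 with an estimated correlation), among them Zbtb16, which encodes PLZF, at 116 against 19.9. Ribosome biogenesis genes fell in 3 of 22, 3 adjusted over the list alone (adjusted p 5.4e-10, but adjusted p = 0.058 with an estimated correlation). A total of 444 genes were called, 292 higher and 152 lower in CD4T, and 238 and 194 after array median centring. The count fell to 213 without CD4T replicate 1 (126 higher and 87 lower), 235 without CD8T replicate 1 (154 and 81) and 273 without CD8T replicate 2 (201 and 72), and treat called 49.

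NK cells and NKT cells share the marker NK1.1, and of the pair CD3ε is named for the NKT sort only. T cell genes were lower in NK, with Cd3e (log2 difference -4.37 ± 0.49, limma adjusted p 2.9e-06), Cd5 (-4.21 ± 0.36), Trgv4 (-4.45 ± 0.39) and Trav9d-3 (-4.78 ± 0.27). Among the largest rises in NK were genes of myeloid cells. Hp, haptoglobin, was at 2539.7 in NK and 2.76 in NKT (8.07 ± 0.41), and Cybb, a subunit of the phagocyte oxidase, at 4063 and 41.3 (6.44 ± 0.46). Clec4a3, a lectin receptor of myeloid cells, rose by 6.61 ± 0.70, Cyp4f18 by 7.21 ± 0.52 and Apoc2 by 6.86 ± 0.61. Among the 107 genes restricted to NK, the largest gaps were those of Klra8, a Ly49 receptor, at 3089 ± 209 and 54.2 ± 20.2 in NKT, and Gzma, granzyme A, at 6430.1 ± 188 and 174 ± 56.9. The 107 held 2 members of the NK and cytotoxic list (Gzma and S1pr5) and 6 of the monocyte and macrophage list (Adgre1, Ccr2, Cd68, Cx3cr1, Klf4 and Ms4a6c).

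Of 18 monocyte and macrophage genes, all 18 rose in NK, 18 adjusted over the list alone (camera adjusted p 2.1e-23, and 0.018 with an estimated correlation). Cx3cr1, a chemokine receptor found on monocytes and on NK cells, was at 2024 in NK and 37.1 in NKT, and Lyz2, lysozyme, at 7155 and 350. Secondary and tertiary granule genes rose in 10 of 13 and 1 fell, 11 and 1 adjusted over the list alone (adjusted p 9.9e-09, but adjusted p = 0.17 with an estimated correlation), with Ngp at 3424 and 231 and Lcn2 at 1095 and 43.5. MHC class II genes rose in 7 of 9, 8 adjusted over the list alone (adjusted p 4.6e-10, and 0.022 with an estimated correlation), with H2-Eb1 at 5402 and 195. B cell genes rose in 7 of 21, 8 adjusted over the list alone, with Ms4a1 at 286 and 39.7 (adjusted p 9.0e-05, but adjusted p = 0.13 with an estimated correlation). Pan T cell genes fell in 16 of 17, 16 adjusted over the list alone (adjusted p 3.7e-15, and 0.00048 with an estimated correlation). Ribosome biogenesis genes fell in 8 of 22, 9 adjusted over the list alone (adjusted p 7.0e-07, but adjusted p = 0.12 with an estimated correlation). In all 1562 genes were called, 945 higher and 617 lower in NK, and 1090 and 457 after array median centring. The number lower was 396 without NK replicate 1 and 411 without NKT replicate 2. Among genes low in both Monocyte and Neutrophil, a restriction chosen after seeing the data, 251 were called, of which 56 were higher and 195 lower in NK. The median of all genes lay at -0.13 and at -0.0022 after array median centring, and treat called 460.

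**Figure D3:**
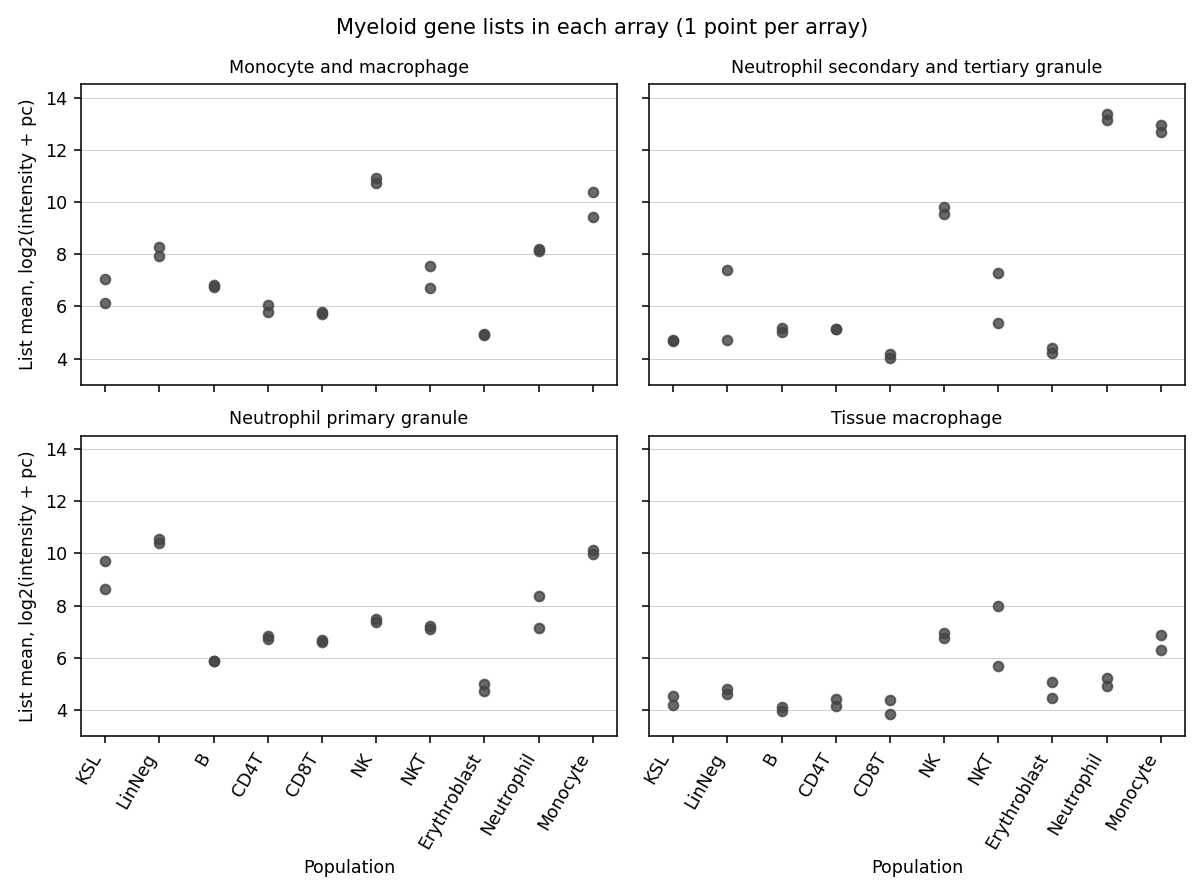
Mean log2(intensity + pseudocount) of 4 myeloid gene lists in each of the 20 arrays, with 1 point per array and populations along the horizontal axis. Both NK arrays hold the monocyte and macrophage list at 10.72 and 10.93, above both Monocyte arrays (9.41 and 10.36), while the NKT arrays lie at 5.70 and 7.99 for the tissue macrophage list.

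NKT cells were then set against the mean of CD4 and CD8 T cells. Genes higher in NKT included Tyrobp, at 1677 in NKT and 42.3 in T cells (log2 difference 5.23 ± 0.38, limma adjusted p 1.4e-07), and Fcer1g, at 1029.8 and 61.6 (4.11 ± 0.27). Cd244a, a receptor of NK cells, rose as well (4.06 ± 0.50). Which cells gave the Tyrobp and Fcer1g signal was not tested. Genes of macrophages were raised too, with Apoe at 435 and 9.31 (4.40 ± 0.56) and Slc40a1, the iron exporter ferroportin, at 619.7 and 12.5 (4.40 ± 0.60). Lyz1, a lysozyme gene, was at 1264 and 3.31 (6.68 ± 0.52), read by a probe set of the kind marked _x_at. Its 2 other probe sets above the filter gave differences of 0.44 and 4.72. Genes lower in NKT included Ccr7, a homing receptor of naive T cells, at 79.3 and 1075 (-3.47 ± 0.38), Il6ra (-4.89 ± 0.40), Itgae (-4.69 ± 0.45) and Igfbp4 (-4.18 ± 0.33). Other probe sets above the filter gave smaller falls, of -0.59 for Il6ra, -1.89 for Itgae and from -3.93 to -1.51 for Igfbp4. Of 22 NK and cytotoxic genes 15 rose and 1 fell, 18 and 1 adjusted over the list alone (camera adjusted p 2.1e-22, and 0.0038 with an estimated correlation), including Ncr1, the receptor NKp46, at 232 and 12.8. Tissue macrophage genes rose in 9 of 12, 11 adjusted over the list alone (adjusted p 7.2e-15, but adjusted p = 0.079 with an estimated correlation), with the complement genes C1qa and C1qb at 166 and 411 in NKT against 2.44 and 15.2. This list stood at 5.70 in NKT replicate 1 and 7.99 in replicate 2 (mean log2 level). Pan T cell genes fell in 3 of 17, 7 adjusted over the list alone (adjusted p 6.7e-05, and 0.015 with an estimated correlation). The contrast called 452 genes, 266 higher and 186 lower in NKT. The number lower was 114 without CD8T replicate 1 and 111 without NKT replicate 1. The count was 220 without NKT replicate 2 (124 higher and 96 lower), where Lyz2 (4.08 with all arrays) fell to 2.92 and was no longer called (adjusted p 0.060). It was 131 among genes low in both Monocyte and Neutrophil, a restriction chosen after seeing the data, and 60 with treat.

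Neutrophil and Monocyte are the Gr-1-positive and Mac-1-positive fractions. The secondary and tertiary granule list had a mean log2 level of 13.26 in Neutrophil and 12.80 in Monocyte, and 1 of its 13 genes, Padi4, was called, as higher in Neutrophil, with 0 adjusted over the list alone (camera adjusted p 0.068). Genes higher in Neutrophil included Ifit1bl2 at 1350.2 ± 444 against 75.1 ± 19.1 (log2 difference 4.03 ± 0.62, limma adjusted p 0.00015), Upp1, uridine phosphorylase (3.17 ± 0.52), Stfa2l1 (2.65 ± 0.47) and Klra17 (2.46 ± 0.42). Monocyte was higher in MHC class II genes, with H2-Aa at 2929 against 43.2 (-6.10 ± 0.55), in Lpl, lipoprotein lipase (-5.46 ± 0.89), in Adgre4 (-5.59 ± 0.79) and in Apoe (-4.96 ± 0.64). It was also higher in Elane, neutrophil elastase of primary granules, at 2675 ± 172 against 133 ± 141 (-4.77 ± 0.77).

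DNA replication genes were lower in Neutrophil in 22 of 23, 22 adjusted over the list alone (camera adjusted p 1.4e-23, but adjusted p = 0.057 with an estimated correlation), with Mcm3 at 52.2 against 529 (-3.18 ± 0.18) and Cdc6 at 16.2 against 341 (-3.91 ± 0.44). Primary granule genes fell in 7 of 9, 7 adjusted over the list alone (adjusted p 0.00041, but adjusted p = 0.17 with an estimated correlation), with Mpo at 286 against 2534 and Prtn3 at 199 against 2034. The 2 Neutrophil arrays stood apart on this list, at a mean log2 level of 7.13 and 8.36, both below the Monocyte arrays (9.99 and 10.14). Monocyte and macrophage genes fell in 10 of 18 and 1 rose, 10 and 1 adjusted over the list alone (adjusted p 2.9e-05, but adjusted p = 0.28 with an estimated correlation), with Ccr2, a chemokine receptor of monocytes, at 29.8 against 1014. MHC class II genes fell in 5 of 9, 5 adjusted over the list alone (adjusted p 9.1e-07, but adjusted p = 0.063 with an estimated correlation). Mature neutrophil receptor genes rose in 4 of 9, 8 adjusted over the list alone (adjusted p 5.7e-06, but adjusted p = 0.057 with an estimated correlation), with Cxcr2 at 1479 against 449. Ribosome biogenesis genes fell in 13 of 22 and 1 rose, 13 and 1 adjusted over the list alone (adjusted p 4.8e-08, but adjusted p = 0.090 with an estimated correlation). There were 1691 called genes, 363 higher and 1328 lower in Neutrophil, and 205 with treat. Without Neutrophil replicate 1, 178 were higher and 990 lower. Of the named genes, Dnah6 and Il1f9 were no longer called without Monocyte replicate 2 (adjusted p 0.062 and 0.075), and Prok2 was not called with the mean of all probe sets (adjusted p 0.11).

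Erythroblasts were compared with the mean of the 7 other mature populations and gave the largest count of the 9 contrasts. Alas2, the first enzyme of heme synthesis in red cells, was at 9412 ± 1951 against a mean of 35.4 (log2 difference 8.42 ± 0.64, limma adjusted p 7.3e-10). Slc4a1, the anion exchanger band 3, rose by 8.42 ± 0.77, Ermap by 8.75 ± 0.45, Kel, a blood group antigen, by 8.42 ± 0.45 and Tspan33 by 8.39 ± 0.34. The largest falls included Ptprc, at 1.85 ± 1.17 against 5590.3 (-9.34 ± 0.10), Coro1a, an actin regulator, at 1.60 against 5317 (-9.29 ± 0.12), Cd52 (-9.53 ± 0.13) and Arhgdib (-8.90 ± 0.11). Laptm5 fell by 8.85 on the log2 scale, but 1 of its other probe sets had the opposite sign, at 2.47.

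Of 22 erythroid genes, 21 rose, 21 adjusted over the list alone (camera adjusted p 2.1e-15, and 0.017 with an estimated correlation), and all 10 heme biosynthesis genes rose, 10 adjusted over the list alone (adjusted p 2.0e-09, and 0.017 with an estimated correlation), with Fech, ferrochelatase, at 11266 against 187. All 23 DNA replication genes rose, 23 adjusted over the list alone (adjusted p 3.2e-13, but adjusted p = 0.15 with an estimated correlation), and all 23 mitosis genes rose, 23 adjusted over the list alone (adjusted p 2.1e-15, but adjusted p = 0.10 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, was at 9504 against 777, and Cdk1 at 5285 against 239. Ribosome biogenesis genes fell in 15 of 22, 15 adjusted over the list alone (adjusted p 0.0018, but adjusted p = 0.31 with an estimated correlation), with Tcof1, a factor of rRNA transcription, at 4.24 against 166 (-3.70 ± 0.21). The mean log2 level of this list in Erythroblast (6.33) lay above Neutrophil (5.64) and near Monocyte (6.67). The lymphoid populations were higher, from 7.68 in NK to 8.80 in CD8T. MHC class II genes fell in 9 of 9, 9 adjusted over the list alone (adjusted p 0.00065, but adjusted p = 0.17 with an estimated correlation). A total of 6459 genes were called, 2464 higher and 3995 lower, against 3083 and 3578 under quantile normalization, and treat called 4026. The Gapdh 3′ to 5′ ratio was highest in this population, at 5.98, and lowest in Neutrophil, at 2.42. The median of all genes lay at -0.13 and shifted by 0.16 under quantile normalization.

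**Figure D4:**
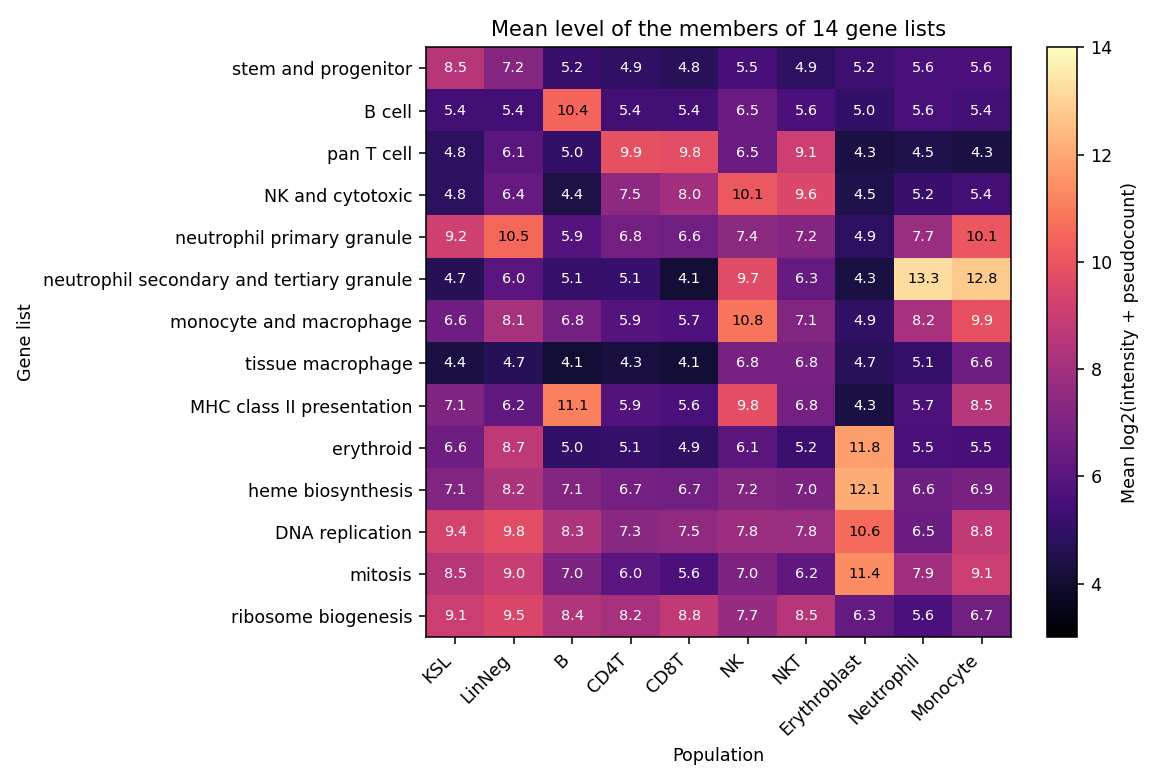
Mean log2(intensity + pseudocount) of the members of 14 gene lists (rows) in the 10 populations (columns), with the value printed in each cell and shown by colour. The monocyte and macrophage list is highest in NK (10.83) and the primary granule list in LinNeg (10.48), while the erythroid list is highest in Erythroblast (11.78) and the B cell list in B (10.44).

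A gene was called restricted to a population when it was called higher there than in each of the 9 others. There were 1491 such genes, of which 915 were in Erythroblast, 154 in B, 138 in Neutrophil, 107 in NK, 95 in KSL, 39 in CD4T, 21 in LinNeg, 13 in NKT, 5 in CD8T and 4 in Monocyte. In B, Tnfrsf13c, which encodes the BAFF receptor, was at 2839 ± 49.0 and at 56.7 ± 20.8 in NK, the next population. In LinNeg, Igha was at 5039 ± 1091 and 51.2 ± 11.6 in CD4T, and the metallothionein genes Mt1 and Mt2 were at 973 ± 476 and 2037 ± 840. In CD4T, Foxp3 was restricted, at 331 ± 20.6 against 22.9 ± 0.818 in Erythroblast. In NKT, the gamma chain variable genes Trgv1 and Trgv4 were at 1459 ± 71.5 and 1309.7 ± 127, against 239 ± 14.3 in NK and 236 ± 55.6 in CD4T, and Cd160, a receptor of cytotoxic lymphocytes, at 809 ± 17.3 against 259 ± 67.4 in CD8T. The 4 genes restricted to Monocyte were Gpx3, Fcnb, Chit1 and Ctdspl, of which Fcnb, a ficolin, was the brightest, at 4267 ± 1202 against 1079.7 ± 355 in Neutrophil. With NK left out of the model, an alternative chosen after seeing the data, Monocyte had 31 restricted genes and NKT 28.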

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

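The tests of all 3 patterns weighed below (NK, NKT and Mac-1 arrays) were chosen only after these results were seen, and of the tests in this part only those of other splits of the samples were set before their values were seen.

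Outside the gene-level comparisons, 10092 probe sets had several gene symbols or none, and 6066 of them lay above the filter. Of these, 366 were restricted to 1 population by the same criteria as the genes, 224 of them to Erythroblast, 65 to B, 26 to Neutrophil and 25 to KSL. They were singled out because they carry signal that no comparison of named genes used, and no gene was read from them.

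Monocyte and granule genes were high in the NK arrays. A single deviating array is argued against, since the lower of the 2 NK arrays held the monocyte list 3.59 (log2) above the NKT mean and the higher one 3.81. Array scaling is argued against as the cause, since the median difference of the list was 4.12 as deposited and 4.30 after quantile normalization. Admixture of the whole Mac-1 gate in one proportion is argued against as the only source of both lists. The monocyte list lay 0.94 above its Mac-1 level, while the secondary and tertiary granule list lay 3.13 below it (a difference of -3.13). The 2 gaps thus differed by 4.07. Such admixture stays open as a source of the granule genes, since the test cannot separate out monocyte genes expressed by the sorted cells. A monocyte-rich admixture in the NK1.1 gate stays open as a candidate source, although the sort was for NK1.1-positive cells. Any step that removed monocytes is not given in the sources used here. In all, 18 of 18 monocyte list members were higher in NK than in NKT. Of the members, 2 are in another list and 14 lay above the filter in CD4T or CD8T. Expression by the sorted NK cells themselves cannot be told apart from admixture without arrays of purer monocytes. Lyz2, a member, was at 7155 in NK and 350.2 in NKT.

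Tissue macrophage genes were high in the NKT arrays, and in replicate 2 other myeloid lists were raised too, with the secondary and tertiary granule list at 7.29 (5.36 in replicate 1) and the monocyte list at 7.54 (6.71). The same admixed cells as in NK are argued against as the only source of the tissue macrophage genes, though not as a source of the other lists, because the NK minus NKT difference was 3.70 for the monocyte list and 0.0050 for the tissue macrophage list, which are 3.69 apart. A signal in 1 array only is argued against, since both NKT arrays were above the mean of the T cell arrays, the lower by 1.505 and the other by 3.79. Macrophages in the NKT gate stay a candidate source, with 9 of 12 members called (3 of the 12 lay above the filter in CD4T or CD8T) and C1qb at 411, and cannot be told apart from expression by the sorted cells, since no array of sorted tissue macrophages was used here. The sort was for cells positive for CD3ε and NK1.1, and any step that removed macrophages is not given in the sources used here.

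Granule genes were high in the Mac-1 arrays. A first test on the secondary and tertiary granule list gave a median difference, Neutrophil minus Mac-1, of 0.19, and was replaced, after that value and the list levels were known, by a test on a wider set of genes with bounds set at that point. Of 80 genes abundant in Neutrophil (mean log2 above 11) and low in B, CD4T and CD8T (below 8), 96.2% lay no more than 2 (log2) lower in the Mac-1 arrays; because the pattern prompted both tests, they could have excluded neutrophil-lineage cells in the Mac-1 gate but cannot establish them, and these cells cannot be told apart from expression of the same genes by the sorted monocytes. The Gr-1 sorted cells are argued against as the source of the primary granule genes, whose median difference, Neutrophil minus Mac-1, was -2.46, with 7 of 9 genes lower in Neutrophil. Neutrophils carry Mac-1, so the gate would not remove them, and immature granulocytes in it may be a source of both sets of genes, as an untested hypothesis.

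For the 4124 genes called between lymphoid and myeloid populations, 1 of 21 ways to pick 2 of the 7 populations gave as many, the real one, and the highest of the others gave 2317. When the 14 arrays were split into 10 and 4 instead, in a model of 2 groups that called 3787 genes, 1 of 100 drawn splits gave as many, the real one, and the highest of the others gave 2412. The real split by population gives the smallest share that 21 ways allow. Neutrophil and Monocyte were closer to each other (mean r 0.917) than to any lymphoid population (highest mean r 0.851, NK with Monocyte). That rank was therefore likely beforehand, and the comparison cannot exclude chance. The splits of arrays part the replicates of a population and so raise the spread within groups, which leaves that comparison without weight of its own.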

How the results depend on the processing

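The alternatives that left NK or Erythroblast out and those restricted to genes low in Monocyte and Neutrophil were chosen after seeing the data. None of the 152 named pairs of gene and contrast and no list reversed its direction under the alternatives in which it was tested. Genes named only as list members, such as Hlf, Procr and Meis1, were not followed in the alternatives. Lists were not tested in those alternatives chosen later or with only the arrays of the compared populations, and the later ones covered 20 pairs of named gene and contrast without Erythroblast, 52 without NK and 8 among the genes low in Monocyte and Neutrophil. The named pairs were chosen from these data for their large differences, so keeping the call says little about called genes in general. They kept the call in 3193 refits and lost it in 15. Of these losses, 13 came in the 1304 refits without 1 array and concern 9 of 152 pairs. Dntt in KSL vs LinNeg lost it with the 5th percentile pseudocount (log2 difference 2.90) and Prok2 in Neutrophil vs Monocyte with the mean of all probe sets (1.07).

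Without a minimum log2 difference, 1176 genes passed in KSL vs LinNeg, 5851 in KSL vs mature, 7724 in lymphoid vs myeloid and 2701 in Neutrophil vs Monocyte. With treat against a log2 difference of 1, which asks more of each gene by construction, the counts were 68 in KSL vs LinNeg, 983 in KSL vs mature, 2421 in lymphoid vs myeloid, 726 in B vs T, 49 in CD4T vs CD8T, 460 in NK vs NKT, 60 in NKT vs T, 205 in Neutrophil vs Monocyte and 4026 in Erythroblast. Among genes low in Monocyte and Neutrophil, where fewer genes were tested, 251 were called in NK vs NKT and 131 in NKT vs T. Leaving out 1 array gave 293 to 660 genes in KSL vs LinNeg, 213 to 342 in CD4T vs CD8T and 220 to 438 in NKT vs T. The lone remaining array of a population is then assumed to vary like the others, and the cause of these changes was not tested. The other total counts stayed within 1.5 times, but the number in a single direction moved further in Neutrophil vs Monocyte (178 higher without Neutrophil replicate 1) and in NK vs NKT (396 lower without NK replicate 1 and 411 without NKT replicate 2), and 10 populations had their 2 arrays nearest each other with quantile normalization, with Spearman in place of Pearson correlation and with no filter on low values, the alternatives run for it.

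Of 113 list calls, 30 held and 83 were lost with an estimated correlation, and the cause was not tested. Of the 113, 29 were lost under at least 1 other alternative, 21 of them without 1 array. The filter at the 75th percentile ended 15 and fry 10.

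Replicate numbers gave no general sign of pairing: deviations of same-numbered arrays correlated from -0.094 to 0.21 over 45 pairs of populations, with 1 pair over 0.1, KSL and LinNeg, which are the sides of a contrast that changed with single arrays. Both also had a wide spread between their 2 arrays on the immediate early list (SD of the mean log2 level 2.18 and 1.91). With the replicate block, 748 genes were called in KSL vs LinNeg, 3181 in KSL vs mature, 4123 in lymphoid vs myeloid, 1818 in B vs T, 445 in CD4T vs CD8T, 1565 in NK vs NKT, 442 in NKT vs T, 1695 in Neutrophil vs Monocyte and 6453 in Erythroblast, and the 113 list calls and 1491 restricted genes had the same counts. The block was a single term shared by all populations, so it was no test of a pairing confined to KSL and LinNeg. Signal over background limits dim genes, whose differences shrink with the pseudocount.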

Other observations

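The hypotheses on Ezh2 and Ezh1 below were written before their values were seen.

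Genes of platelets and mast cells were not described above. Pf4, platelet factor 4, was at 1485 ± 389 in LinNeg, 557 ± 257 in KSL and 156 ± 69.9 in NK (SD, n = 2), and at most 49.9 in the other populations. Itga2b, the platelet integrin chain CD41, was at 521 ± 159.9 in KSL and 380.1 ± 94.7 in LinNeg. Mcpt8, a protease of basophils, was at 445 ± 493 in LinNeg, so that its 2 arrays differed by more than its mean. The secondary and tertiary granule list also split the LinNeg arrays, at a mean log2 level of 4.70 in replicate 1 and 7.39 in replicate 2.

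Levels of some chromatin genes varied by population. Bmi1 was between 410.1 and 509.8 in KSL, LinNeg and the lymphoid populations, and at 51.6 ± 14.1 in Neutrophil and 26.0 ± 6.04 in Erythroblast. Tet2, a DNA demethylase, was at 534 ± 83.1 in NK and 4.76 ± 3.94 in Erythroblast, and Dnmt3b at 561 ± 71.2 in LinNeg and 11.5 ± 9.59 in Erythroblast. Ezh2, the catalytic subunit of Polycomb repressive complex 2, was at 2565 ± 107 in Erythroblast, 1308 ± 52.3 in LinNeg and 175 ± 108 in Neutrophil, and the list of that complex was lower in Neutrophil than in Monocyte (3 of 11 genes, camera adjusted p 0.018, but adjusted p = 0.10 with an estimated correlation and 0.072 with the filter at the 75th percentile).

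One hypothesis was that Ezh2 rises and Ezh1 falls with proliferation across populations. It was tested as the correlation of population means with the mean of the mitosis list over 10 populations, by a two-sided permutation test with 100000 resamples, in a family of 69 chromatin genes. The permutation treats the populations as exchangeable, but some are closely related. The mean r was 0.929 for KSL and LinNeg, 0.938 for CD4T and CD8T, and 0.917 for Neutrophil and Monocyte. The permutation p-values may therefore overstate the evidence. For Ezh2, Spearman's rho was 0.73 (permutation p 0.020, adjusted p 0.12) and Pearson's r 0.81 (permutation p 0.0042, adjusted p 0.036). Without the 2 populations farthest from the median, Erythroblast and CD8T, r was 0.66. For Ezh1, rho was -0.37 (permutation p 0.30, adjusted p 0.64) and r -0.19 (permutation p 0.60, adjusted p 0.76), and r was -0.83 without the same 2 populations, and Erythroblast had the highest mitosis mean and the highest Ezh1 level. By Spearman's rho, 0 of the 69 genes passed an adjusted p of 0.05 and 16 an unadjusted p of 0.05, and by Pearson's r 11 and 24 did. The data leave both parts of the hypothesis open.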
